A study of Mus musculus with 10 samples.

How the data were processed

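Total RNA of mouse hepatocytes was measured on 10 oligonucleotide arrays of 12488 probe sets each, 1 array per sample. Per the labels, the samples form 4 groups: 2 normoxic untreated, 2 normoxic adeno-treated, 3 hypoxic adeno-treated wild type and 3 hypoxic HIF-1alpha null, with no normoxic null sample. The labels also number the samples 1 to 3 within each group. The adeno vector, whether the null cells were adeno-treated, the way HIF-1alpha was removed, the genotype of the normoxic cells, the oxygen level and time of the hypoxia, and whether each array stands for a separate culture are not given in the sources used here. The deposited values are of the unit intensity, on a linear scale. They carry the authors' scaling: the mean between the 2nd and 98th percentile, computed here, was between 200.0 and 200.4 on every array, and the medians were between 60 and 70.9. The steps from the scans to these values are not given in the sources used here. For arrays, the number of arrays limits the precision.

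The scaling was kept, 4.7 (the 10th percentile of all values) was added to each value, and log2 was taken. Folds are therefore ratios on the scale of value plus 4.7, and group means are plain intensities. The 66 control probe sets and the probe sets dimmer than the 40th percentile of the mean over all 10 arrays were left out, which left 7453 probe sets to test. A table of the platform pairs 10855 probe sets with 1 gene symbol, 396 with several and 1237 with none. Of the 10855, 10839 matched a gene of the mouse reference annotation GRCm38.p6, which was used for names only, and 16 did not. Of the probe sets tested, 6724 carried 1 symbol, for 5688 genes. Some probe sets whose names end in f, s or r may hybridise with related transcripts.

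Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit on the 4 group means of all 10 arrays, then eBayes with an intensity trend, 6 residual degrees of freedom), tested on both sides, and adjusted by Benjamini-Hochberg over the 7453 probe sets of a comparison, with a threshold of 0.05. Every adjusted p given for a probe set is from limma. The comparisons were hypoxic wild type against normoxic adeno-treated, hypoxic null against hypoxic wild type, hypoxic null against normoxic adeno-treated, and normoxic adeno-treated against normoxic untreated. A further result was how many of the probe sets called in hypoxic wild type were also called in hypoxic null cells, and the slope through 0 of the null on the wild-type log2 changes. A simulation of unchanged groups on the shared arrays, with a component shared by arrays of the same number, was run 100 times beside it.

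The 28 gene lists, 22 of pathways and 6 of markers of other cell types, hold 680 entries. Matched to reference gene symbols and synonyms, with repeats within a list counted once, they gave 669. Each was tested with limma's camera with a preset correlation of 0.01, 2-sided, and adjusted over the 28 lists of a comparison, with 1 probe set per gene (the brightest). Members past the threshold were counted over all probe sets tested and adjusted over the list alone. The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule names, among probe sets with 1 symbol past the threshold and with no overlap between the 2 groups of arrays, the 12 largest rises and 12 largest falls in each of the first pair of comparisons and the 5 and 5 in the others. Where none passes, it names the 5 of smallest p. It adds 16 genes chosen for their link to hypoxia or hepatocytes, and up to 4 members of smallest p per list. Other genes are named as chosen after their values were seen.

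Whether the sample numbers pair the arrays was checked on the deviations of each array from its group mean. Among the 6 hypoxic arrays, same-number pairs correlated at r of 0.542 to 0.678 and different-number pairs at -0.518 to -0.146. Deviations sum to 0 within a group, which in part forces such negative values. On the log2 values themselves, 6 of 6 hypoxic arrays correlated best, among hypoxic arrays, with the array of the same number. On the deviations, all 13 same-number pairs correlated above 0.1, the lowest at 0.106. The normoxic number 2 arrays, whose deviations mirror those of number 1 in groups of 2, correlated with the hypoxic number 3 arrays (0.149 to 0.251) as well as with the hypoxic number 2 arrays (0.106 to 0.177). The numbers were read as pairing the samples on the hypoxic arrays, with weaker support on the normoxic ones, on which the block counts against normoxic groups rest. The fit with a replicate block (4 residual degrees of freedom) is given beside the results that it changes: it called 111 probe sets higher in hypoxic wild type, against 24 without it. In that fit the number 3 arrays enter the comparisons with normoxia only through null minus wild type, since no normoxic array has number 3.

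The alternatives were offsets of 2.35 and 18.8, no filter and a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, array weights, the replicate block, only the 2 groups compared, all 4 normoxic arrays as control, disjoint controls, camera with an estimated correlation, and each array left out in turn. Alternatives without the number 3 arrays, a replicate block with arrays left out and a replicate block with quantile normalization were added after the data were seen. A count is called changed where it moved by over 1.5 times. The scripts were tested on simulated data: in 20 datasets of 7453 probe sets with 200 changed, limma recovered 82.8% of changes of log2 2 in the first comparison, 86.8% in the second, 82.0% in the third and 74.1% in the fourth. At log2 1 it recovered 33.7%, 46.3%, 36.4% and 26.6%. The mean numbers of false calls were 1.95, 2.5, 1.5 and 1.2. With the replicate block, 91.0%, 93.2%, 88.9% and 87.8% of changes of log2 2 were recovered, with 6.65, 8.45, 7.4 and 6.8 false calls.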

Results

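The data were 10 arrays of mouse hepatocyte RNA in 4 groups: 2 normoxic untreated, 2 normoxic adeno-treated, 3 hypoxic adeno-treated wild type and 3 hypoxic HIF-1alpha null. HIF-1alpha is the oxygen-regulated subunit of a transcription factor that turns on genes in low oxygen. Values below are scaled intensities as mean ± SD, with n the number of arrays. Any pair of arrays correlated at r of 0.897 to 0.971 across probe sets, which are not independent replicates. The 18S ribosomal control probe sets of the 2 hypoxic number 3 arrays read 12.18 and 12.33 on the log2 scale, against 5.98 to 10.25 on the 4 normoxic arrays and 7.38 to 8.97 on the other hypoxic arrays. Between hypoxic number 3 and number 1 arrays, the median log2 difference of 18 stellate cell and fibroblast markers was -1.58, of 28 hepatocyte genes 0.32 and of 19 urea cycle and amino acid genes 0.98. The number 2 arrays lay between for these lists: from number 1 to 2 the medians were -0.39, 0.21 and 0.45, and from 2 to 3 they were -1.22, 0.06 and 0.63. The normoxic groups hold no number 3 array.

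**Figure D1:**
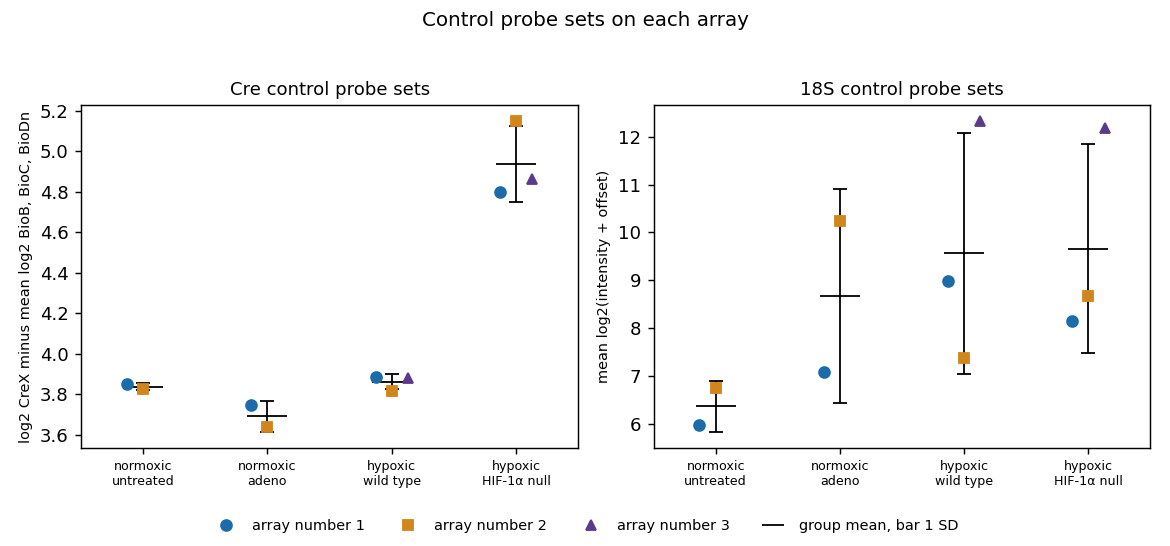
Control probe sets on each of the 10 arrays, by group (horizontal). The left panel plots the mean log2 of the CreX probe sets with names ending in at minus that of the BioB, BioC and BioDn spike-in probe sets. The right panel plots the mean log2(intensity + 4.7) of the 18S probe sets. Symbols and colours give the array number, and black lines the group mean with a bar of 1 SD. The left value averaged 4.94 on the 3 null arrays and 3.81 on the other 7, and the right value was highest, at 12.18 and 12.33, on the 2 number 3 arrays.

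The comparison of hypoxic adeno-treated wild-type with normoxic adeno-treated cells asks how these hepatocytes respond to hypoxia. Adm, which encodes the vasodilator peptide adrenomedullin, showed the largest rise: 2401 ± 659 (SD, n = 3) in hypoxia against 84.2 ± 7.78 (SD, n = 2), 26.4-fold. Slc2a1, the glucose transporter GLUT1, was 1754 ± 79.9 (n = 3) against 182 ± 18.7 (n = 2), 9.44-fold. Hk2, the hexokinase that starts glycolysis, was 397 ± 81.3 (n = 3) against 65.2 ± 22.8 (n = 2), 5.83-fold. Pgf, a growth factor for blood vessels, was 594 ± 219 (n = 3) against 81.2 ± 4.74 (n = 2), 6.61-fold. In limma these were log2 changes of 4.72 (SE 0.28, adjusted p = 7.96e-05), 3.24 (SE 0.20, adjusted p = 7.96e-05), 2.54 (SE 0.26, adjusted p = 0.00359) and 2.72 (SE 0.43, adjusted p = 0.0310).

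Atf3 and Fos also rose in hypoxic wild-type cells. The stress-induced transcription factor gene Atf3 was 1737 ± 640 (n = 3) against 203 ± 14.3 (n = 2), 8.01-fold (limma adjusted p = 0.00359). Fos, a subunit of the factor AP-1, was 268 ± 58.7 (n = 3) against 44.6 ± 4.88 (n = 2), 5.46-fold (limma adjusted p = 0.0111). Gadd45a, a gene of the response to DNA damage, rose by 2.16 on the log2 scale, and Ddit3, a factor of the endoplasmic reticulum stress response, by 1.78. Grpel2, a cofactor of the mitochondrial chaperone, rose by 2.54, and the tight junction gene Cldn4 by 2.48. The transcriptional repressor gene Mnt also rose, but read only 21.2 and 15.9 on the normoxic adeno-treated arrays, so the size of the rise depends on the offset (log2 2.45 with 2.35 added, 1.80 with 18.8 added). Ero1a, an oxidase of protein folding, rose by 1.96 and cyclin G2 (Ccng2) by 1.85. On the normoxic untreated arrays Ccng2 read 258.3 and 223.7 against 139.7 and 107.0 on the adeno-treated ones, and Grpel2 134.7 and 119.0 against 63.7 and 76.8. Against all 4 normoxic arrays Ccng2 did not pass (1.37, adjusted p = 0.0607) and Grpel2 did (2.13, 0.0172). The other genes that rose were H2-Ab1, which encodes a class II antigen-presenting chain (1.67), Ndrg1 (1.45 and 1.26 on 2 probe sets), Pkp2 of desmosomes (1.40), the circadian repressor Bhlhe40 (1.33), Tiparp (1.32), the kinase gene Pim1 (1.26) and Zfand2a (1.18). A second probe set did not pass for Ero1a (adjusted p = 0.536), Pkp2 (0.92, adjusted p = 0.187) and Pim1 (1.63, adjusted p = 0.272).

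Several well-known hypoxia genes did not pass in wild type in limma. Vegfa, the main growth factor of blood vessels, was 544 ± 296 (n = 3) against 76.1 ± 9.76 (n = 2), log2 2.61 (SE 0.54, adjusted p = 0.123), and 2.21 (adjusted p = 0.00505) with the replicate block. Egln1, the oxygen-sensing prolyl hydroxylase that marks HIF-1alpha for degradation, was 703 ± 25.7 (n = 3) against 344 ± 51.5 (n = 2), log2 1.03 (adjusted p = 0.222), and 0.91 (adjusted p = 0.0339) with the replicate block. Against all 4 normoxic arrays both Vegfa (2.57, adjusted p = 0.0196) and Egln1 (1.09, 0.0384) passed. The mitophagy gene Bnip3 was at log2 0.91 (adjusted p = 0.682). The glycolytic genes Pgk1 (-0.04), Ldha (0.05) and Aldoa (0.03 and 0.22 on 2 probe sets) lay near 0 under the deposited scaling, and Pgk1 turned to 0.01 under quantile normalization. The factor genes Hif1a (0.19 and 0.33), Arnt (0.37) and Epas1 (-0.27), and Epo (0.15), did not pass. Pck1, of glucose synthesis, was at -0.56, and at -1.11 (adjusted p = 0.0491) with the replicate block, and albumin (Alb) was at -0.16. Alb was the brightest probe set on most arrays, and quantile normalization gives such a probe set nearly the same value on every array. The 0.07 of Alb under that setting was therefore fixed in advance and says nothing about its change. Egln3 and Car9 have no probe set with their symbol.

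Of 7453 probe sets, 24 were higher in hypoxic wild type, for 20 genes, and 0 were lower in limma. At an unadjusted p under 0.05 there were 591, of which 333 were higher and 258 lower. The 2 groups of arrays did not overlap for any of the 24, which their selection by p makes likely. Over all 7453 probe sets tested, 1846 had no overlap, and chance gives no overlap in 20%. With the replicate block, 111 were higher and 55 lower, and the 24 were all among them. The 24 fell to 3 without normoxic adeno number 2, to 8 without normoxic adeno number 1 and to 5 without hypoxic wild-type number 2, where a lone normoxic array is assumed to vary like the other groups. The 111 and 55 with the replicate block became 21 and 2 without normoxic adeno number 2, 64 and 8 without number 1, 66 and 24 without hypoxic wild-type number 1, 47 and 16 without number 2, and 72 and 23 without number 3.

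Known targets of HIF were higher as a list in hypoxic wild type, a call that ended with an estimated correlation. Of 27 tested members outside glycolysis, 22 were positive, with a median log2 change of 0.71. Over all probe sets 4 passed (Adm, Ero1a, Bhlhe40 and Ndrg1). Of the 27, 11 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.57e-11; adjusted p = 0.135 with an estimated correlation). The 19 members of glycolysis and glucose uptake had a median of 0.18, with Slc2a1 and Hk2 called. There were 4 higher when adjusted over the list alone (camera adjusted p = 3.21e-05; adjusted p = 0.245 with an estimated correlation). Of 17 immediate early genes, Fos was called and 6 were higher when adjusted over the list alone, among them Myc (0.91) and Nr4a1 (0.94). The median was 0.40 (camera adjusted p = 3.94e-04; adjusted p = 0.245 with an estimated correlation). The 11 circadian and nuclear receptor regulators had a median of 0.43, with Bhlhe40 called. Adjusted over the list alone, 3 were higher, among them Nr1d1 (0.99) and Nfil3 (0.91) (camera adjusted p = 0.00314; adjusted p = 0.245 with an estimated correlation). That call ended with no filter (adjusted p = 0.129).

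Of 21 genes of the unfolded protein and integrated stress response, Atf3 and Ddit3 were called and 3 were higher when adjusted over the list alone, with Atf4 at 0.86. The median was 0.19 (camera adjusted p = 0.00918; adjusted p = 0.245 with an estimated correlation). That call ended with the replicate block (adjusted p = 0.0720, and 0.0683 without the number 3 arrays) and with no filter (0.0625). The 19 interferon and antigen presentation genes were lower as a list (median -0.13, camera adjusted p = 0.0401; adjusted p = 0.541 with an estimated correlation). So were 24 proliferation genes (median -0.23, 0.0403; adjusted p = 0.743 with an estimated correlation) and 13 heat shock proteins (median -0.26, 0.0474; adjusted p = 0.312 with an estimated correlation). None of their members was called over all probe sets. Adjusted over the list alone, 0 interferon, 0 proliferation and 2 heat shock members were lower, the latter being Hspa1b (-1.24) and Hspa8 (-0.63). Each of these 3 calls ended under quantile normalization (adjusted p = 0.0515 for each), and those of the interferon (0.165) and heat shock (0.0741) lists also with no filter. That of proliferation ended with the replicate block (0.206), without the number 3 arrays (0.150) and with both (0.139).

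With the replicate block, liver metabolism lists also passed in hypoxic wild type, in the direction of lower values, though no list in that fit passed with an estimated correlation (lowest adjusted p = 0.0681). The medians were -0.46 for 19 urea cycle and amino acid genes (camera adjusted p = 1.64e-04, against 0.465 without the block) and -0.27 for 36 oxidative phosphorylation genes (8.77e-06, against 0.0893). They were -0.30 for 29 cytochrome P450 and drug metabolism genes (0.00144, against 0.258) and -0.24 for 28 hepatocyte identity genes (0.00206, against 0.152). Of the urea cycle list, 4 were called lower, among them Tat, which degrades tyrosine (-1.37), and Tdo2, which degrades tryptophan (-1.50). The tricarboxylic acid cycle (0.0121), fatty acid oxidation (0.0207) and gluconeogenesis (0.0119) lists passed in the same direction. Markers of other cell types were higher in the same fit. The 18 stellate cell and fibroblast markers had a median of 0.61 (camera adjusted p = 2.20e-06, against 0.465 without the block). Medians were 0.56 for 5 biliary markers (6.96e-04, against 0.129) and 0.31 for 11 macrophage markers (0.00300, against 0.0885). Whether the share of cell types differed between these groups was not tested apart from these lists.

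**Figure D2:**
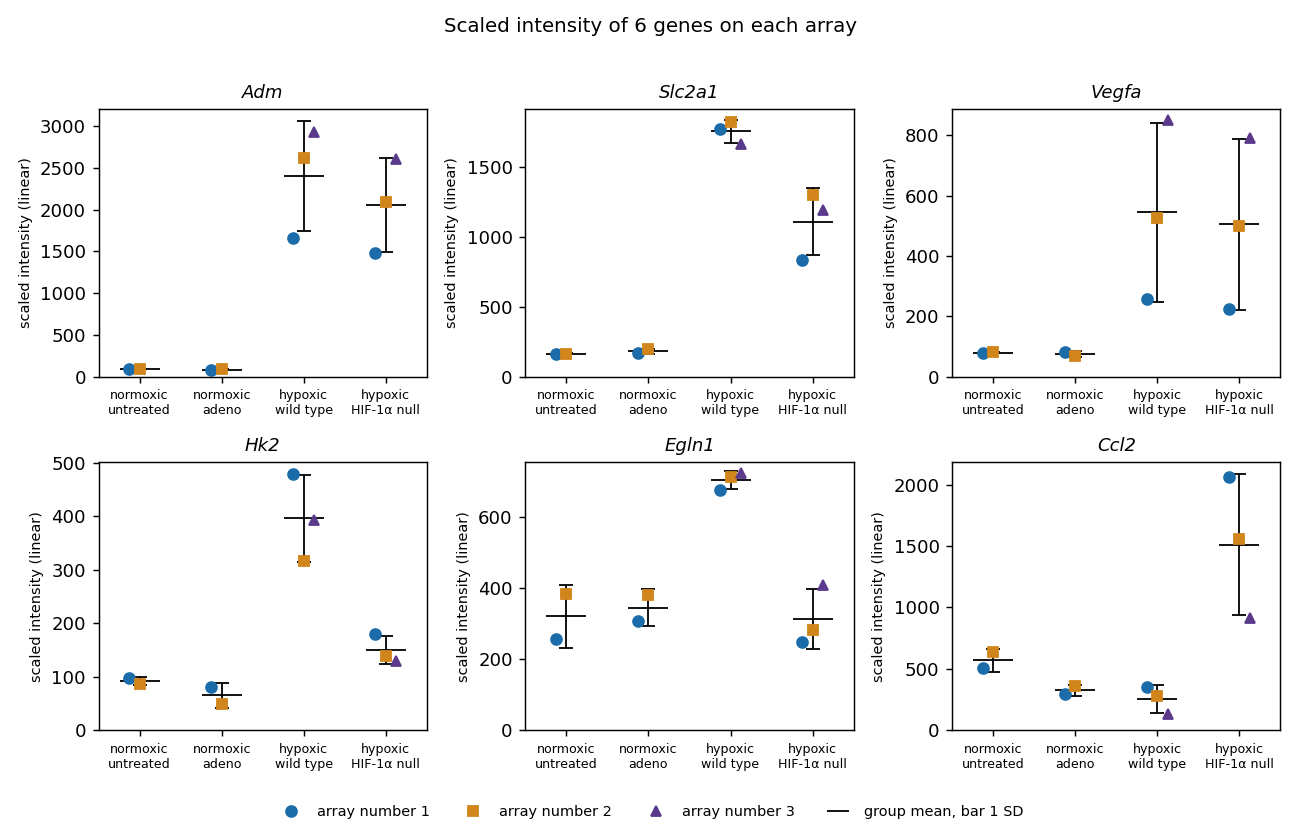
Scaled intensity on a linear axis (vertical) of 6 genes on each of the 10 arrays, by group (horizontal). Symbols and colours give the array number, and black lines the group mean with a bar of 1 SD. Adm, Slc2a1 and Vegfa were high on all 6 hypoxic arrays, Hk2 and Egln1 were higher on hypoxic wild-type than on hypoxic null arrays, and Ccl2 averaged 1510 on the null arrays against 255 on hypoxic wild-type arrays.

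The comparison of hypoxic null with hypoxic wild-type cells asks what the missing HIF-1alpha changes under hypoxia. The labels do not say whether the null cells were adeno-treated, so any difference in that treatment is held in it too. Ccl2, a chemokine that attracts monocytes, was 1510 ± 576 (SD, n = 3) in null against 255 ± 111 (SD, n = 3), 5.96-fold, and higher in 3 of 3 same-number pairs. Hk2 was 150 ± 26.5 (n = 3) against 397 ± 81.3 (n = 3), and Egln1 313 ± 85.3 (n = 3) against 703 ± 25.7 (n = 3), both lower in 3 of 3 pairs. Pfkl, the liver phosphofructokinase, was 800 ± 99.6 (n = 3) against 1503 ± 426 (n = 3). F9, clotting factor IX, was 161 ± 19.1 (n = 3) against 317 ± 58.3 (n = 3). None of these passed without a block. The smallest adjusted p of the comparison was 0.310, that of Ccl2 (log2 2.57, SE 0.37), and Hk2 was at -1.37 (SE 0.24, adjusted p = 0.327).

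With the replicate block, Ccl2 rose (2.57, SE 0.17, adjusted p = 2.46e-04) and 9 probe sets fell. They were Hk2 (-1.37, adjusted p = 0.0278), Sdc2, a heparan sulfate proteoglycan (-0.97, 0.0330), Egln1 (-1.19, 0.0341) and F9 (-0.94, 0.0444). The others were the glycogen synthase gene Gys1 (-1.05, 0.0444), the translation factor gene Eif1b (-0.90, 0.0444), Pfkl (-0.87, 0.0444), Fam162a (-0.96, 0.0484) and Ak4, a mitochondrial adenylate kinase (-1.03, 0.0484). Sdc2, F9, Gys1, Eif1b, Pfkl and Ak4 were chosen after their values were seen. Each of the 9 was lower in 3 of 3 pairs, which their selection by a fit on these pairs makes likely. Among the 5 genes of smallest p without a block, Nampt, of the salvage of nicotinamide, was 81.9 ± 7.04 (n = 3) against 207 ± 34.3 (n = 3) in limma (-1.28, adjusted p = 0.0547 with the block). Bid, which promotes cell death, was 185 ± 7.47 (n = 3) against 90.0 ± 0.902 (n = 3) in limma (adjusted p = 0.0752 with the block).

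Adm, with the largest rise in wild type, differed between null and wild-type cells under hypoxia by -0.22 on the log2 scale and Vegfa by -0.12, and neither passed. Slc2a1 was 1109 ± 242 (n = 3) against 1754 ± 79.9 (n = 3) in limma (-0.68, SE 0.18, adjusted p = 0.649, and 0.116 with the replicate block), lower in 3 of 3 pairs. Bnip3 (-0.83), Ldha (-0.31), Pgk1 (-0.25), Aldoa (-0.18 and -0.46) and Alb (-0.01) did not pass. Both Hif1a probe sets read higher on the arrays labelled HIF-1alpha null: 1169 ± 422 (n = 3) against 792 ± 147 (n = 3) and 1247 ± 400 (n = 3) against 837 ± 224 (n = 3) in limma (0.52 and 0.56, adjusted p = 0.999 for both), each higher in 3 of 3 pairs. Where the deletion lies relative to these probe sets is not given in the sources used here, so they check nothing about the genotype.

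In limma, 0 probe sets were higher and 0 lower, with 252 at an unadjusted p under 0.05, 126 in each direction. The replicate block gave 1 higher and 9 lower. The 9 became 0 without hypoxic wild-type number 2 or 3 or null number 2 or 3, 2 without wild-type number 1 and 15 without null number 1, and the 1 became 6 without wild-type number 1 and 12 without null number 1. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 0 calls and the highest other 1; a test of 3 against 3 arrays taken 1 gene at a time could not go below an exact p of 0.1.

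As lists, glycolysis and HIF targets were lower in hypoxic null than in hypoxic wild-type cells, calls that ended with an estimated correlation (adjusted p = 0.0732 for each). Of 19 glycolysis members, 16 were negative, with a median of -0.31. Over all probe sets 0 were called in limma, and 8 were lower when adjusted over the list alone, among them Hk2, Pdk1, which holds pyruvate out of the mitochondrial cycle (-1.15), Pgm1 (-0.60) and Pfkl (camera adjusted p = 7.80e-12; adjusted p = 0.0732 with an estimated correlation). Of 27 other HIF targets, 23 were negative, with a median of -0.34. Over all probe sets 0 were called in limma, and 6 were lower when adjusted over the list alone, among them Ak4 (-1.22 on the brighter of its probe sets), Egln1, Mxi1 (-0.87) and the collagen prolyl hydroxylase P4ha2 (-0.70) (camera adjusted p = 4.29e-11; adjusted p = 0.0732 with an estimated correlation). Of 24 proliferation genes, 21 were positive, with a median of 0.24, as in Ccne1 (0.64) and Mcm2 (0.40). Even adjusted over the list alone, 0 passed in limma (camera adjusted p = 8.32e-04; adjusted p = 0.886 with an estimated correlation). Of 28 hepatocyte identity genes, 22 were negative, with a median of -0.12, and F9 alone was lower when adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.886 with an estimated correlation). This call ended under quantile normalization (0.125) and without the number 3 arrays (0.0945). The other 24 lists did not pass. For HIF pathway components (median 0.21, mean 0.07), lymphocyte markers (0.19, 0.04) and heat shock proteins (0.02, -0.03) the test leaned to lower values. Of the 6 marker lists of other cell types, the lowest adjusted p was 0.435.

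The comparison of hypoxic null with normoxic adeno-treated cells holds the genotype, the hypoxia and any difference in adeno treatment together, since there is no normoxic null group and the labels of the null cells name no such treatment. Adm was 2058 ± 561 (SD, n = 3) against 84.2 ± 7.78 (SD, n = 2), 22.6-fold, and Slc2a1 1109 ± 242 (n = 3) against 182 ± 18.7 (n = 2), 5.88-fold. Grpel2 was 612 ± 186 (n = 3) against 70.3 ± 9.26 (n = 2), 7.98-fold, and Atf3 was 1648 ± 439 (n = 3) against 203 ± 14.3 (n = 2), 7.78-fold. Pgf was 615 ± 266 (n = 3) against 81.2 ± 4.74 (n = 2), 6.67-fold, and Cldn4 was 1322 ± 273 (n = 3) against 205 ± 74.9 (n = 2), 6.44-fold. In limma the log2 changes were 4.50 for Adm (SE 0.28, adjusted p = 1.70e-04), 2.56 for Slc2a1 (SE 0.20, 4.99e-04), 2.96 for Atf3 (SE 0.31, 0.00472), 2.74 for Pgf (SE 0.43, 0.0306) and 2.69 for Cldn4 (SE 0.39, 0.0200), and the adjusted p of Grpel2 was 0.00784.

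Among the falls, the lectin receptor gene Cd302 was 395 ± 11.96 (n = 3) against 1336 ± 478 (n = 2) in limma (-1.70, adjusted p = 0.0192). Tbl1xr1, of a transcriptional corepressor (-1.49, adjusted p = 0.0169), the chaperone gene Hspa1b (-1.43, 0.0373) and Hsd17b4, of fatty acid oxidation in peroxisomes (-1.19, 0.0447), also fell. Mbd1, which binds methylated DNA, fell by 1.55 (270 ± 84.5, n = 3, against 776 ± 34.5, n = 2, limma adjusted p = 0.0393), but was 274 ± 56.5 (n = 2) on the normoxic untreated arrays, and did not pass against all 4 normoxic arrays (-0.80, adjusted p = 0.426). Hsd17b4 did not pass under quantile normalization (0.0609) or median centring (0.0766). Vegfa was at 2.49 (adjusted p = 0.122, and 2.09, 0.00514, with the replicate block, and 2.45, 0.0206, against all 4 normoxic arrays). Hk2 was at 1.17 (0.136, and 1.21, 0.00834, with the block) and Egln1 at -0.16. Hif1a was at 0.71 and 0.88, and rose by 0.85 and 1.03 with the replicate block (adjusted p = 0.0150 and 0.00343). Pck1 was at -0.61, and fell to -1.16 (0.0264) with it. Arnt (0.33), Epas1 (-0.06), Bnip3 (0.08), Pgk1 (-0.29), Ldha (-0.25), Aldoa (-0.15 and -0.24), Epo (-0.01) and Alb (-0.17) did not pass. Alb was at 0.04 under quantile normalization, which holds so bright a probe set nearly level.

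In limma, 26 probe sets were higher, for 23 genes, and 6 lower, for 6 genes, with 726 at an unadjusted p under 0.05; the replicate block gave 220 and 211. The 26 and 6 became 5 and 1 without normoxic adeno number 1, 3 and 0 without number 2, 4 and 1 without null number 2, and 11 and 0 without null number 3, and the 6 became 3 without null number 1. The 220 and 211 became 84 and 29 without normoxic adeno number 1, 34 and 16 without number 2, 56 and 40 without null number 2, and 114 and 117 without null number 3.

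In hypoxic null cells, 17 immediate early genes had a median of 0.45 over the normoxic adeno-treated cells, with Fos called (1.82). There were 7 higher when adjusted over the list alone, among them Myc and Dusp1 (0.70) (camera adjusted p = 4.83e-05; adjusted p = 0.357 with an estimated correlation). Of 21 unfolded protein and integrated stress response genes, Atf3 and Ddit3 (2.06) were called and 5 were higher when adjusted over the list alone (median 0.13; camera adjusted p = 0.00474; adjusted p = 0.357 with an estimated correlation). Circadian regulators (11, median 0.28, 1 called; 0.0486; adjusted p = 0.357 with an estimated correlation) were higher, a call that ended with the replicate block (0.0832), quantile normalization (0.0736), no filter (0.485), without the number 3 arrays (0.121) and with the block as well (0.116). Of 28 hepatocyte identity genes, 27 were negative, with a median of -0.24. Over all probe sets 0 were called in limma, and 1, Cebpa, a factor of liver differentiation (-0.95), was lower when adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.537 with an estimated correlation). The 29 cytochrome P450 and drug metabolism genes were lower (median -0.17, camera adjusted p = 0.0217; adjusted p = 0.663 with an estimated correlation). So were 13 heat shock proteins, with Hspa1b called (median -0.32, 0.0337; adjusted p = 0.357 with an estimated correlation). Under quantile normalization the last 3 calls ended (0.0578, 0.0784 and 0.0736). The 27 other HIF targets had a median of 0.01 and a mean of 0.38 (0.0680), and the 19 glycolysis members a median of -0.07 and a mean of 0.12 (0.956), so neither list passed.

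With the replicate block, the null cells also had lower metabolic lists than the normoxic adeno-treated cells, though no list in that fit passed with an estimated correlation (lowest adjusted p = 0.146). The urea cycle and amino acid genes had a median of -0.58, with 10 of 19 called lower, among them Tat at -1.56 and Arg1, the last enzyme of the cycle, at -0.86 (camera adjusted p = 8.45e-05). Oxidative phosphorylation (median -0.30, 1.40e-05), gluconeogenesis (0.00275, with G6pc at -1.61), fatty acid oxidation (0.00276) and iron and oxidative stress (0.0439) were also lower. The p53 targets were higher in that fit (camera adjusted p = 0.0349, against 0.0756 without the block). So were the biliary (3.91e-04, against 0.0756), macrophage (0.0382, against 0.274) and stellate (median 0.41, 6.02e-04, against 0.956) markers. The stellate list leaned to lower values without the block (median -0.01). Here too, the change from normoxia in the fit with the block rests on numbers 1 and 2.

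How far the hypoxic response of wild type was seen in the null cells was counted over probe sets. Of the 24 higher in hypoxic wild type in limma, 17 were also higher in hypoxic null cells against the same normoxic arrays, and 0 were lower in null than in wild type under hypoxia, though 14 of the 24 lay below wild type. That 0 was fixed in advance and tests nothing, since 0 of the 7453 probe sets were called lower in null than in wild type. Under independence, which the shared normoxic arrays break, 0.0837 would be shared. Over the 24, the slope of the null on the wild-type changes was 0.92. With the replicate block, 90 of 111 were higher in both, 44 of 55 lower in both, and 3 of the 111 were lower in null than in wild type. With normoxic untreated arrays as the control of wild type, so that no control array was shared, 9 of 14 were higher in both. The slope was 0.84 over those 14 and 2 called lower. In the simulation, unchanged groups with shared arrays and a component shared by same-number arrays gave a correlation of 0.671 between the changes over all probe sets. The simulated component had the same size on normoxic and hypoxic arrays. In the data, the deviations of same-number pairs that include a normoxic array correlated at 0.106 to 0.379, against 0.542 to 0.678 between hypoxic arrays. The 0.671 may therefore be too low, and the observed 0.767 cannot be judged against it. The 17 became 4 without normoxic adeno number 1, 3 without number 2, 4 without hypoxic wild-type number 2, 11 without number 3, 4 without null number 2 and 11 without null number 3.

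**Figure D3:**
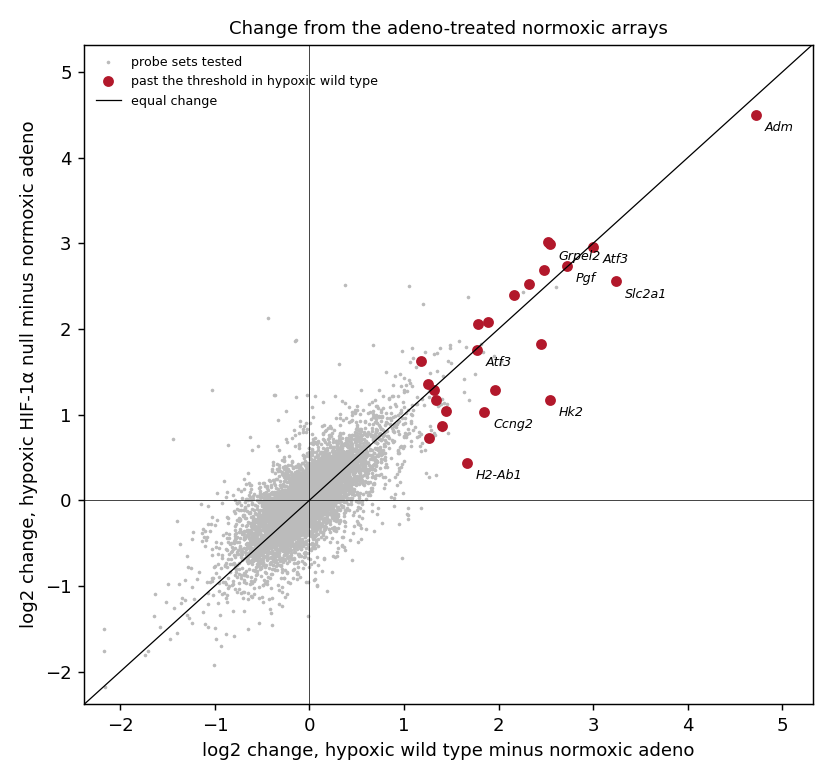
Log2 change from the normoxic adeno-treated arrays in hypoxic wild type (horizontal) and hypoxic null (vertical), 1 point per probe set tested. Red points are the 24 probe sets past the threshold in wild type, and the line marks equal change. All 24 lie above 0 on both axes. Hk2 (2.54 against 1.17) and H2-Ab1 lie farthest below the line among the labelled genes, and both axes use the same normoxic arrays.

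The comparison of normoxic adeno-treated with untreated cells asks what the adeno treatment does on its own. The 5 genes of smallest p did not pass in limma, each at an adjusted p of 0.498. One of them carries the symbol of a microRNA, which was not matched to the probe set, and no value is given for it. Mbd1 was at 776 ± 34.5 (SD, n = 2) against 274 ± 56.5 (SD, n = 2). Zfp36l1, which speeds the decay of messenger RNA, was at 334 ± 42.6 (n = 2) against 912 ± 7.42 (n = 2). Man2c1, a mannosidase, was at 647 ± 35.2 (n = 2) against 309 ± 1.06 (n = 2), and Ptms at 4605 ± 299 (n = 2) against 2655 ± 192 (n = 2). All 5 passed with the replicate block. Mbd1 rose 2.83-fold (adjusted p = 0.0313), Man2c1 by 1.05 on the log2 scale (0.0386) and Ptms by 0.79 (0.0313). Zfp36l1 fell by 1.44 (0.0313). The hypoxia genes Adm (-0.20), Slc2a1 (0.15), Vegfa (-0.08), Egln1 (0.12), Bnip3 (-0.33), Epo (0.41) and Hif1a (-0.18 and -0.27) did not pass, nor did Alb (0.58). Alb was at -0.07 under quantile normalization, which holds so bright a probe set nearly level. In limma 0 were higher and 0 lower, with 620 at an unadjusted p under 0.05, and the replicate block gave 8 and 11. The 8 became 27 without normoxic untreated number 1 and 1 without untreated number 2, adeno number 1 or adeno number 2. The 11 became 0 without untreated number 2 or adeno number 2 and 1 without adeno number 1.

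None of the 28 lists passed in that comparison. Proliferation genes (24 members, median 0.25, with Mcm2 at 0.53) and cytoskeleton genes (21, median 0.28, with the actin regulator Cfl1 among the highest) had the lowest adjusted p, 0.0998 each, and both passed with the replicate block (camera adjusted p = 0.0189 for each; adjusted p = 0.938 with an estimated correlation). Interferon and antigen presentation genes had a median of -0.03 (adjusted p = 0.976), and acute phase genes one of -0.07 (0.976).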

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

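The tests of the Cre and 18S probe sets, of RNA quality, of the share of hepatocytes as the whole cause, of cells that kept HIF-1alpha, and of the splits with the replicate block were chosen only after the results they measure were seen. The differences between null and wild-type cells under hypoxia that passed in the fit named are given first. The log2 differences with the replicate block were 2.574 for Ccl2, -1.373 for Hk2, -0.974 for Sdc2, -1.189 for Egln1 and -0.9423 for F9. They were -1.048 for Gys1, -0.8971 for Eif1b, -0.8692 for Pfkl, -0.958 for Fam162a and -1.03 for Ak4. As lists without the block, the medians were -0.3059 for glycolysis, -0.3385 for other HIF targets, -0.1166 for hepatocyte identity and 0.2354 for proliferation. All 4 list calls ended with an estimated correlation (camera adjusted p = 0.0732, 0.0732, 0.886 and 0.886), and that of hepatocyte identity also under quantile normalization (0.125) and without the number 3 arrays (0.0945).

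Beside these, all 10 of the 10 splits of the 6 hypoxic arrays gave at least the 0 calls of the real split in limma without a block. With 0 calls that outcome was fixed in advance and tests nothing. The highest other split gave 1 call. In that fit of the real split, 252 probe sets lay at an unadjusted p under 0.05. For the lists, 7 of the 10 splits gave at least the 4 lists of the real one, and the highest other gave 15. The 6 splits that part only 1 number pair called 4 to 15 lists, which points to a structure of the samples by number. Among the 4 splits that part all 3 number pairs, 1 gave as many calls with the replicate block as the real split, which was the real one itself with 10 calls, against 0 in the highest other. Those 4 splits called 4, 3, 0 and 0 lists. In the real one the camera adjusted p was 7.80e-12 for glycolysis and 4.29e-11 for other HIF targets. In the others, camera gave adjusted p of 2.28e-07 and 0.00530, 0.485 and 0.0613, and 0.949 and 0.433. The small camera p of both lists thus also arose in 1 split with wrong labels. These other splits keep the real labels on most arrays, so part of a real difference would remain in them. In all 3 counts the splits are too few for a share under 0.05.

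The Cre control probe sets with names ending in at were higher on the null arrays, a signal outside the comparisons. The 3 prime and 5 prime CreX probe sets with names ending in st are left out of the values below. Null minus the other 7 arrays, they differed by -0.52 and -0.23 on the log2 scale (exact permutation p = 0.258 and 0.55). The CreX probe sets minus the BioB, BioC and BioDn spike-in probe sets averaged 4.94 ± 0.19 (SD, n = 3) on the null arrays and 3.81 ± 0.09 (SD, n = 7) on the others, a log2 difference of 1.132 (exact permutation p = 0.00833, the smallest that 120 splits can give). More of the whole spike-in mixture would raise the other spike-in probe sets as well, and those differed by -0.22 (exact permutation p = 0.3). On both the 3 prime and the 5 prime CreX probe set ending in at, 3 of 3 null arrays lay above all 7 others, which restates the difference and supports no source of it. Cre transcripts in the null cells cannot be told apart from a spike-in mixture with more CreX alone, since both would raise these probe sets, and how HIF-1alpha was removed is not given in the sources used here.

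Arrays with the same number deviated together, and the 18S probe sets on the hypoxic number 3 arrays lay on average 2.008 above the highest normoxic array on the log2 scale. A lower share of hepatocytes on the number 1 than on the number 3 arrays may contribute: on number 3 the stellate list was lower in 18 of 18 genes (median -1.577, exact sign test adjusted p = 1.07e-04) and the hepatocyte list higher in 21 of 28 (0.32, adjusted 0.0351), while the endothelial (-1.23, 3 of 4 lower, 0.734), biliary (-0.69, 5 of 5, 0.148) and macrophage (-0.46, 8 of 11, 0.373) lists had the same sign as the stellate one and did not pass. These sign tests count genes, which vary together within a list, and not samples, so their p measures no spread between arrays. Whether a lower share of hepatocytes was the whole cause cannot be told apart from a cause that moves each list by its own amount. The 4 marker lists differed at a permutation p = 0.1087 over 38 genes, which are not independent replicates. Stellate genes such as Acta2 (2384 to 2601 in the group means) were abundant in every group. RNA quality or ribosomal carry-over stays open too: the 18S values followed the first component over the 10 arrays at rho = 0.6606 (permutation p = 0.0431, adjusted 0.0647 over 3 relations) and r = 0.772 (permutation p = 0.00945, adjusted 0.0215), which fell to 0.418 without the 2 farthest arrays and so rests on those, and the 3 prime minus 5 prime values gave a rho of 0.00606 for beta-actin and -0.673 for Gapdh (adjusted 0.0647), whose r of -0.732 (adjusted 0.0215) became -0.211 without the 2 farthest arrays. These values were taken as deviations from their group means and permuted freely over the 10 arrays. In the groups of 2 such deviations mirror each other, so the permutation p values may be too small. Apart from the share of cell types, weighed here as a mixed sample, no biological explanation was tested, since the design has no group by number.

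Most probe sets higher in hypoxic wild type were also higher in hypoxic null cells, 17 of 24, with a slope of 0.92. With disjoint normoxic controls the slope was 0.8442, over the 14 probe sets higher and 2 lower in that setting, a set other than the 24. Shared control arrays alone therefore do not account for the slope in that set. Untreated and adeno-treated normoxic arrays of the same number still deviated together (r = 0.379), so the setting does not remove the structure by number. Cells that kept HIF-1alpha, as the whole cause, would keep the same share of every rise, but with the replicate block the shares differed beyond their errors (heterogeneity chi-square 212.7 on 23 degrees of freedom, chi-square p = 1.14e-32, with errors that share arrays). They ran from 15.9% ± 10.9 (SE) for H2-Ab1 and 26.3% ± 4.81 for Hk2 to 85.3% ± 9.08 for Adm, 101% ± 10.5 for Pgf and 168% ± 30.9 for Zfand2a. A response that needs HIF-1alpha for some genes more than for others may account for the spread, and it stays untested without a normoxic null group, as do some cells that kept HIF-1alpha beside it.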

How the results depend on the processing

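Settings without the number 3 arrays, with arrays left out under the replicate block, and with the replicate block and quantile normalization together were chosen after the results were seen. Over 99 named probe set results, 1566 alternatives kept the direction and side of the threshold, 55 passed it only in the alternative and 89 lost it. Another 77, for 28 of the results, turned sign without passing in either setting, among them Pgk1 in hypoxic wild type under quantile normalization. No call reversed. Over 108 list results, 498 stayed on the same side of the threshold, where the direction of a list not past it was not counted, 55 gained and 36 lost a call, and 3 reversed: the stellate list in hypoxic null against normoxic adeno-treated cells turned from lower (adjusted p = 0.956, not past) to higher with the replicate block (adjusted p = 6.02e-04), without the number 3 arrays (0.00330) and with both (0.00108). The 108 leave out some of the 28 lists of each comparison. Those left out were called and lost their call with an estimated correlation, so the 36 understates the losses. The slope kept between 0.84 and 0.94 in every setting that left in all arrays of numbers 1 and 2. The cause of a change was not tested, except that fewer arrays or genes entered where a setting leaves them out.

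For the 24 higher and 0 lower in hypoxic wild type, array weights gave 42 and 2, the replicate block 111 and 55, all 4 normoxic arrays 38 and 5, the replicate block without number 3 arrays 72 and 23, and the block with quantile normalization 101 and 47. Only the 2 groups compared gave 6 higher, and 4 times the offset, no filter and median centring each gave 1 lower. For the 0 and 0 in null against wild type under hypoxia, 1 was higher with array weights, without the number 3 arrays, and in each fit with the replicate block (alone, without number 3 arrays, with quantile normalization). The replicate block gave 9 lower, and 11 with quantile normalization. For the 26 and 6 in hypoxic null against normoxic adeno-treated cells, array weights gave 106 and 64, the replicate block 220 and 211, only the 2 groups compared 11 and 0, all 4 normoxic arrays 44 and 17, no number 3 arrays 16 and 1, the block without them 114 and 114, and the block with quantile normalization 179 and 188. No intensity trend gave 3 lower. For the adeno treatment (0 and 0), the replicate block gave 8 and 11, and 1 higher with quantile normalization. The 17 higher in both became 35 with array weights, 90 with the replicate block, 9 with disjoint controls, 27 with all 4 normoxic arrays, 4 with only the groups compared, 11 without the number 3 arrays and 54 with the block as well, and the 0 higher in wild type and lower in null became 3 with the block.

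Of the gene lists, the 8 past in hypoxic wild type became 0 with an estimated correlation, 16 with the replicate block, 5 with quantile normalization, 4 with no filter, 15 without number 3 arrays and 16 with the block as well. Glycolysis and glucose uptake and the other canonical HIF targets were at adjusted p = 0.245 and 0.135 with an estimated correlation, and at most 1.64e-04 (replicate block) and 1.08e-08 (replicate block, without the number 3 arrays) in the other settings. The 4 past in null against wild type under hypoxia became 0 with an estimated correlation, where both lists were at 0.0732, against at most 5.77e-10 (replicate block) and 2.43e-09 (no filter on dim probe sets). The 6 past in hypoxic null against normoxic adeno-treated cells became 0 with an estimated correlation, 14 with the replicate block, 2 with quantile normalization, 13 without number 3 arrays and 14 with the block as well. The 0 of the adeno treatment became 2 with the replicate block.

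Leaving out 1 array at a time, the higher and lower counts ranged from 3 to 18 and 0 to 0 in hypoxic wild type, 0 to 0 and 0 to 0 in null against wild type, 3 to 20 and 0 to 3 in null against normoxic, and 0 to 0 and 0 to 0 for the adeno treatment. The lowest for hypoxic wild type and for null against normoxic came without normoxic adeno number 2. Those higher in both ranged from 3 to 16, those higher in wild type and lower in null from 0 to 0, and the slope from 0.86 to 0.96. Where a hypoxic array was left out, the 0 lower in null was fixed in advance, since no probe set was called lower in null than in wild type. The ranges under the replicate block were 21 to 72 and 2 to 24, 1 to 12 and 0 to 15, 34 to 160 and 16 to 160, and 1 to 27 and 0 to 13. Signal over background limits dim genes: the offset of 4.7 shrinks their folds, and those under the 40th percentile were not tested.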

Other observations

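The single genes in this part and the differences by array number were picked after their values were seen, from tests of lists and probe sets set beforehand apart from those by number. Inflammatory genes other than Ccl2 were uneven between null and wild-type cells under hypoxia. Saa3, an acute phase protein, was 254 ± 133 (SD, n = 3) in null against 56.4 ± 27.2 (SD, n = 3) and, with Ccl2, was higher when adjusted over its list alone, but did not pass over all probe sets (2.01, limma adjusted p = 0.632). Cd14, a receptor for bacterial lipopolysaccharide, was at -0.74 (adjusted p = 0.999). The 24 acute phase genes had a median of 0.02 and did not pass (0.557), nor did 19 interferon and antigen presentation genes (median 0.18, 0.0906).

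Cebpa, a factor of liver differentiation, was 651 ± 131 (SD, n = 3) in hypoxic wild type and 685 ± 112 (SD, n = 3) in hypoxic null against 1315 ± 52.0 (SD, n = 2) in normoxic adeno-treated cells. It did not pass in limma (adjusted p = 0.125 and 0.136), but fell with the replicate block by 0.88 (adjusted p = 0.00781) and 0.79 (0.00912). In hypoxic wild type against normoxic adeno-treated cells, the median of 14 cholesterol synthesis genes was -0.11 (camera adjusted p = 0.552) and that of 13 lipogenesis genes -0.03 (0.843). The 4 endothelial markers had a median of 0.23 (0.474), and the 2 erythroid markers one of -0.23 (0.465). Between hypoxic number 3 and number 1 arrays, differences among the largest were -4.25 for Cyp1a1, which oxidises aromatic compounds, -3.87 for the biliary keratin Krt7, 3.86 for Cyp26a1, which degrades retinoic acid, and 3.57 for the iron hormone gene Hamp. All 36 oxidative phosphorylation genes were higher on number 3 (median 0.53), as were 13 of 13 lipogenesis genes (0.69).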
